A study of Homo sapiens with 6 samples.

How the data were processed

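Poly(A) RNA was sequenced from 6 libraries of NCI-H1437, an established human line of non-small cell lung cancer. The labels place 3 libraries in a group called control blank, with columns named WT, and 3 in a CHD6 knockout group. They do not say whether the control cells went through any editing or selection step. Each column of the deposited table was matched to its library by its name. The labels call the libraries biological replicates, and nothing in them says that they came from separate cultures, so the p-values measure the spread between these libraries.

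The authors deposited 1 table of whole-number read counts for 20345 Ensembl genes, not normalized. The submitters' processing notes name HISAT2, StringTie and the human build hg19, without roles or versions. The gene annotation, the counting step and its use of strand are not given in the sources used here. Reads that match near-identical genes could have been split or dropped, which makes levels of SAA1 and SAA2, the MAGEA genes, KRT6A and KRT6B, the AKR1C genes, the HLA genes and the histone genes uncertain. Counts of overlapping or antisense genes share the same doubt. Gene-level counts do not show which exons were covered.

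Gene symbols were taken by Ensembl identifier from a table of gene names, which matched 19446 of the 20345 identifiers. Older list symbols were matched through RefSeq synonyms of assembly GRCh38.p14, which was also used for the order of neighbouring genes, and no coordinates were carried between builds. The gene with identifier and symbol CHD6 (ENSG00000124177) was the targeted gene.

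Library totals ranged from 28795584 to 40019116 counts, so that 1 count corresponded to 0.0250 to 0.0347 CPM. A count of 0 over a group was given a floor of 3 counts over its 3 libraries, which is 0.0299 CPM in the knockout-labelled group and 0.0259 CPM in the control group. Genes at 0 in a group are reported as at least N-fold different from that floor. For genes with 1 to 3 counts in a group, the ratio has a 95% counting interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

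Genes with low counts were removed with edgeR's filterByExpr, which left 14147 genes. Counts were scaled by TMM factors and fitted with edgeR's quasi-likelihood model on the group, and every gene was tested, two-sided, with Benjamini-Hochberg adjustment. The threshold was an adjusted p under 0.05. A second count used an absolute log2 fold change of at least 1. The standard error (SE) of a log2 fold change was its size over the square root of the F statistic. CPM were computed on TMM-scaled library sizes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

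Before the data were examined, 47 gene lists were fixed, covering pathways, complexes, lung and other lineages, and markers of other cell types. The 45 lists with at least 5 tested members were compared with all other genes by limma's camera test (preset correlation 0.01) on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was run beside it. The fry test asks whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. List counts of higher and lower genes use the adjustment over all genes tested. Counts adjusted over the list alone were the same in 45 of the 47 lists, and the other 2 are given beside their counts. List medians were also computed with every gene at 0 in a group set to its bound.

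The rule for named genes was fixed at the same time. It took CHD6, the 10 highest rises and 10 largest falls among genes past the threshold, with a mean of at least 5 CPM over all 6 libraries, non-overlapping groups and a proper symbol. From each called list it took the 4 members with the smallest adjusted p in the list's direction and the 2 called against it. From the NRF2 targets it took the 4 with the smallest p, with NFE2L2 and KEAP1. Some genes that the rule takes are not reported here. Genes outside this rule are said to be chosen after their values were seen.

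The code was tested on simulated counts for the same 14147 genes, with 50 genes changed at each size. Of these, edgeR recovered 50% at 1.2-fold, 86% at 1.5-fold, 94% at 2-fold and 100% at 3-fold, and 7 calls (4.07%) were false. Among 46 simulated lists, which included a made list of 30 raised genes, camera called no other list at an adjusted p under 0.05. The genes were drawn independently, so the simulation cannot show how often camera falsely calls lists of correlated genes. A far larger share of genes changed in the data, and the adjustment depends on that share. The simulated recovery therefore need not hold there.

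Libraries were compared before averaging. The chi-square per gene was 4.18 to 5.00 within groups, above the value of about 1 that sampling noise alone gives, so no library repeated another.

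Alternatives were another scaling (DESeq2's size factors), no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, DESeq2, limma-voom, an adjusted p under 0.01, a test against a 1.2-fold change, and leaving out each library in turn. Scaling by library totals alone was added after the data were seen.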

Results

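Poly(A) RNA was counted per gene in 6 libraries of NCI-H1437, a human non-small cell lung cancer line. Of these, 3 carry the label control blank, called control here, and 3 the label CHD6 knockout. CHD6 is a chromatin remodeller of the CHD family, and the series title sets it beside KEAP1, the adaptor that directs the transcription factor NRF2 to degradation. The comparison of the groups asks which transcripts differ when CHD6 is targeted. The control libraries held 38979180, 37229745 and 36452860 counts and the knockout-labelled libraries 40019116, 34294576 and 28795584. Levels are CPM as mean ± SD with n = 3 libraries per group, and log2 fold changes are knockout-labelled over control.

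CHD6 RNA was not lower in the libraries labelled CHD6 knockout. It stood at 47.4, 48.1 and 47.9 CPM in the control libraries and at 55.5, 61.3 and 56.0 CPM in the knockout-labelled libraries. The group means were 47.8 ± 0.349 and 57.6 ± 3.21 CPM, a log2 fold change of 0.27 (SE 0.0423, adjusted p = 6.458e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 3 of 3 libraries). The gene-level counts do not show which CHD6 exons were read, and an edited gene can keep its RNA. All directions given here therefore refer to the label, and whether CHD6 protein was lost was not measured. KEAP1 had 0, 2 and 5 counts in the control libraries and 0 in each knockout-labelled library, where a count of 0 over the group allows up to 0.0299 CPM, and it was too low to test. Whether the gene is silent, deleted, edited or missed in counting was not tested. NFE2L2, the gene of NRF2, rose from 113 ± 3.37 to 137 ± 4.72 CPM (log2 fold change 0.28, SE 0.0339, adjusted p = 5.862e-06).

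Most expressed genes differed between the groups. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11595 of 14147 genes changed (81.96%), 5812 higher and 5783 lower in the knockout-labelled libraries. Of these, 2455 were at least 2-fold higher and 1778 at least 2-fold lower. The near-even split depends on the scaling, since library totals alone gave 5336 genes higher and 6357 lower. The groups did not overlap for 11812 genes (83.49%), where chance gives 10%. Spearman correlations over genes were 0.9894 to 0.9904 within groups and 0.9485 to 0.9497 between them, and the biological coefficient of variation was 5.33%. Mitochondrial transcripts made up 5.78 ± 0.147% of counts in the control libraries and 4.68 ± 0.0315% in the knockout-labelled libraries. The labels give no batch, so any difference in culture or handling between the groups has the same split as the label. Of 45 gene lists tested, camera called 26, of which 14 were higher and 12 lower, and 8 were also called with an estimated correlation.

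Among changed genes with a mean of at least 5 CPM over all 6 libraries, the 10 that rose most were inflammatory, antimicrobial, interferon-induced and matrix genes. S100A8, a calcium-binding subunit of calprotectin, rose from 2.59 ± 0.115 to 3865 ± 120 CPM (log2 fold change 10.54, SE 0.0350, adjusted p = 9.925e-21). S100A7, with no count in the control libraries, reached 58.5 ± 1.03 CPM, at least 2254-fold higher. The acute phase genes SAA1 and SAA2 were at least 1110-fold and at least 850.0-fold higher, with reads that cannot be assigned surely between these similar genes. PGLYRP3, a peptidoglycan recognition protein, was at least 836-fold higher, and the chemokine gene CXCL10 at least 517-fold higher. The interferon-induced genes HERC5 and GBP5 were at least 470.0-fold and at least 413-fold higher. LUM, the gene of the matrix proteoglycan lumican, was at least 476-fold higher. DCN, the gene of decorin, had 2 counts in the control libraries and 33.0 ± 1.89 CPM in the knockout-labelled libraries, a ratio of 1921 (95% counting interval 531 to 15866).

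Under the same minimum, the 10 largest falls included germline, lineage and metabolic genes. MAGEA12, a cancer testis antigen gene, fell from 38.4 ± 0.751 CPM to no count, at least 1284-fold lower. MAGEA4 fell from 42.0 ± 1.93 CPM to 3 counts over the group, a ratio of 1404 (95% counting interval 480.2 to 6812), and CSAG1, a neighbouring antigen gene, fell from 15.7 ± 1.35 to 0.0686 ± 0.119 CPM. The transcription factor gene SOX21 fell from 21.6 ± 0.814 to 0.0761 ± 0.0601 CPM, and the keratin gene KRT4 from 164 ± 2.67 to 0.616 ± 0.179 CPM. The imprinted gene PEG10 fell from 67.5 ± 1.72 to 0.335 ± 0.195 CPM. CYP1A1, a xenobiotic-metabolising enzyme induced by the aryl hydrocarbon receptor, fell from 430.0 ± 15.8 to 4.42 ± 0.404 CPM (log2 fold change -6.61, SE 0.05004, adjusted p = 1.063e-17). GPAT2, AMBP and SCARA5 had log2 fold changes of -6.38, -5.88 and -5.79.

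**Figure D1:**
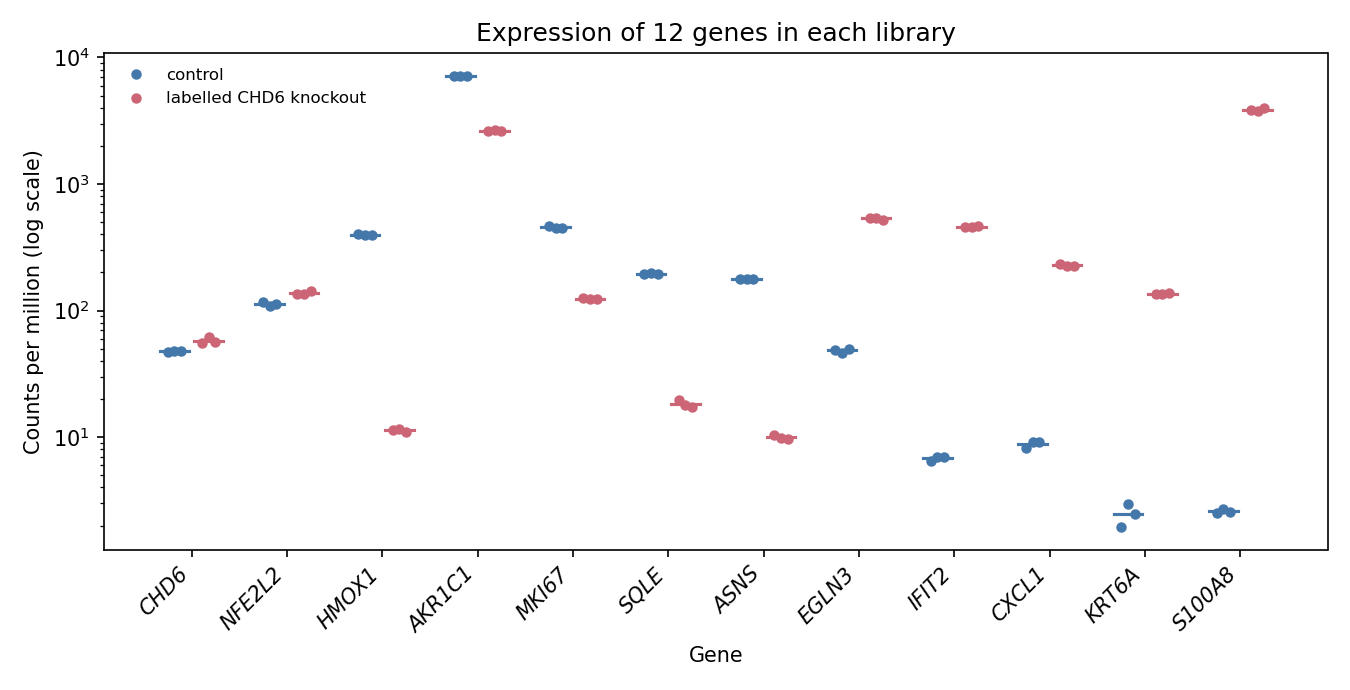
CPM on a log axis for 12 genes, with 1 point per library (3 control, 3 labelled CHD6 knockout) and a bar at each group mean. HMOX1 lies at 397 CPM in the control group and 11.3 CPM in the knockout-labelled group, S100A8 at 2.59 and 3865 CPM, and CHD6 at 47.8 and 57.6 CPM.

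Targets of NRF2, which serve antioxidant defence and NADPH supply, fell as a group. Of 34 NRF2 targets tested, 30 fell and 4 rose, with a median log2 fold change of -1.25 (camera adjusted p = 1.829e-07, and 0.0349 with an estimated correlation). HMOX1, the haem-degrading enzyme, fell from 397 ± 5.16 to 11.3 ± 0.345 CPM (log2 fold change -5.13, SE 0.0313, adjusted p = 1.565e-18). The aldo-keto reductase genes AKR1C1 and AKR1B10 fell by 1.43 and 1.89 on the log2 scale, where AKR1C1 could share reads with its paralogs. Against the group, the transporter gene ABCC3 rose from 381 ± 4.04 to 764 ± 2.85 CPM, and the thioredoxin reductase gene TXNRD1 rose by 0.32. The list of iron and ferroptosis genes, which shares HMOX1 with the NRF2 targets, had 15 lower and 5 higher of 21 (camera adjusted p = 0.03771, and 0.203 with an estimated correlation). Scaled by library totals alone, the iron list lost its call (adjusted p = 0.0553). In it FTL, the ferritin light chain, fell by 1.82 and TFRC, the transferrin receptor, by 0.92, while the lipid enzyme gene ACSL4 rose by 2.91. In the KEAP1 and NRF2 machinery, 7 genes were higher and 4 lower of 11 (camera adjusted p = 0.2014).

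Genes of cell division fell. All 35 mitosis genes tested fell, with a median log2 fold change of -1.63 (camera adjusted p = 3.724e-12, and 0.0349 with an estimated correlation). MKI67, a marker of cycling cells, fell from 454 ± 7.52 to 124 ± 1.38 CPM (log2 fold change -1.87, SE 0.0219), and TOP2A and TPX2 fell by 1.55 and 1.90 on the log2 scale. Of 39 DNA replication genes, 38 fell, with a median of -1.32 (camera adjusted p = 5.722e-11, and 0.0349 with an estimated correlation). The helicase subunit genes MCM2, MCM5 and MCM7 fell by 1.54, 1.78 and 1.62, and CCNE1, the gene of cyclin E1, rose by 1.26. Of 29 DNA repair genes, 28 fell, PARP1 by 1.75 and FANCI by 1.48, and PALB2 rose by 0.25 (camera adjusted p = 1.829e-07, and 0.0733 with an estimated correlation). Of 29 MYC targets, 27 fell, including the nucleolin gene NCL by 1.46 and the polyamine enzyme gene ODC1 by 2.37, while LDHA rose by 0.59 (camera adjusted p = 1.829e-07, and 0.0901 with an estimated correlation). Histone genes had 9 higher and 2 lower of 11, with H2AC6 and H1-2 rising by 2.33 and 2.07 and H2AC20 falling by 2.01 (camera adjusted p = 0.02737, and 0.1519 with an estimated correlation). Poly(A) libraries would miss histone transcripts without a poly(A) tail, so these counts do not give total histone RNA. The histone call was lost without control replicate 1 or without any 1 of the 3 knockout-labelled libraries, at camera adjusted p of 0.0552 to 0.0623, and without a low-count filter, at 0.0714.

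Lipid and amino acid synthesis genes fell. Of 20 cholesterol synthesis genes, 17 fell and 2 rose, with a median of -1.58 (camera adjusted p = 2.82e-05, and 0.0450 with an estimated correlation). SQLE, the squalene epoxidase gene, fell from 196 ± 0.539 to 18.2 ± 1.18 CPM (log2 fold change -3.42), and IDI1 fell by 2.58. Of 13 fatty acid synthesis genes, 11 fell, including the desaturase genes SCD by 2.50 and FADS2 by 4.92 (camera adjusted p = 0.0009881, and 0.1142 with an estimated correlation). Of 25 ATF4 and amino acid response genes, 19 fell and 3 rose (camera adjusted p = 9.421e-05, and 0.1551 with an estimated correlation). ASNS, the asparagine synthetase gene, fell from 178 ± 1.18 to 10.00 ± 0.314 CPM and PSAT1, of serine synthesis, from 299 ± 5.32 to 28.0 ± 0.665 CPM, while VLDLR and CEBPB rose by 1.63 and 1.39.

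Respiratory chain genes fell, while hypoxia genes rose. Of 49 nuclear oxidative phosphorylation genes, 40 fell and 5 rose, with a median of -0.54 (camera adjusted p = 6.098e-07, and 0.1186 with an estimated correlation). CYC1 of complex III fell by 1.88 and ATP5PB of the ATP synthase by 1.12, and ATP5PO rose by 0.24. Of 13 mitochondrial transcripts, 12 fell, with a median of -0.24, MT-CO3 by 0.42 (camera adjusted p = 0.009148, and 0.3583 with an estimated correlation). Of 20 hypoxia genes, 19 rose, with a median of 1.80 (camera adjusted p = 4.384e-07, and 0.0450 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase gene, rose from 48.4 ± 1.69 to 534 ± 9.69 CPM, and ERO1A rose by 2.89 and ANGPTL4 by 2.97 on the log2 scale. Of 22 glycolysis genes, 19 rose and 2 fell, the glucose transporter gene SLC2A1 by 1.82 and PGK1 by 0.84, with GPI falling by 0.67 (camera adjusted p = 0.0002923, and 0.1597 with an estimated correlation).

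Interferon, antigen presentation and NF-kB genes rose. Of 34 interferon response genes, 30 rose and 4 were not called, with a median of 3.84 (camera adjusted p = 1.769e-09, and 0.0428 with an estimated correlation). IFI44 rose from 0.487 ± 0.141 to 463 ± 6.34 CPM, IFIT2 from 6.82 ± 0.303 to 458 ± 4.30 CPM, and ISG15 from 4.04 ± 0.400 to 293 ± 5.08 CPM. Of 19 antigen presentation genes, 18 rose, with a median of 1.89 (camera adjusted p = 1.027e-06, and 0.0428 with an estimated correlation). B2M, the invariant class I subunit, rose by 2.06 and TAPBP by 2.07, while NLRC5, a class I transactivator, fell by 0.26. Of 24 NF-kB and inflammatory genes, 23 rose and 1 was not called, with a median of 3.46 (camera adjusted p = 6.858e-08, and 0.0349 with an estimated correlation). The chemokine genes CXCL8 and CXCL1 rose by 4.53 and 4.69, and BIRC3 and TNFAIP3, both NF-kB targets, by 4.66 and 4.91. Leukocyte markers were not called as a group, with 5 higher and 3 lower of 9 (camera adjusted p = 0.3142).

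The squamous and basal, the epithelial, and the integrin and laminin lists were higher as groups, with members that fell in each. Of 17 squamous and basal genes, 13 rose and 2 fell, with a median of 3.20 (camera adjusted p = 0.001723, and 0.0873 with an estimated correlation). KRT17 rose from 12.4 ± 0.625 to 301 ± 6.18 CPM, and KRT6A and KRT6B, which share sequence, rose by 5.78 and 6.32. SOX2 went from 0.719 ± 0.392 CPM to no count, at least 24.3-fold lower, and DSC3 fell by 0.62 with its call lost without control replicate 2 or 3 or knockout replicate 1 or 3, at edgeR adjusted p of 0.0560 to 0.0873. Of 26 epithelial genes, 20 rose and 3 fell, CDH1, the gene of E-cadherin, by 1.34, with CLDN3 falling by 2.99 (camera adjusted p = 0.0002923, and 0.0787 with an estimated correlation). Of 21 integrins and laminins, 15 rose and 6 fell (camera adjusted p = 0.009638, and 0.140 with an estimated correlation). LAMB3, a laminin chain, rose by 2.81, COL17A1 by 4.01, and LAMB1 fell by 1.28. The cancer testis list had 9 lower and 1 higher of 11, and 10 lower when adjusted over the list alone, with MAGEA3 falling by 0.88 and MAGEC2 rising by 1.90 (camera adjusted p = 0.001734, and 0.0908 with an estimated correlation).

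**Figure D2:**
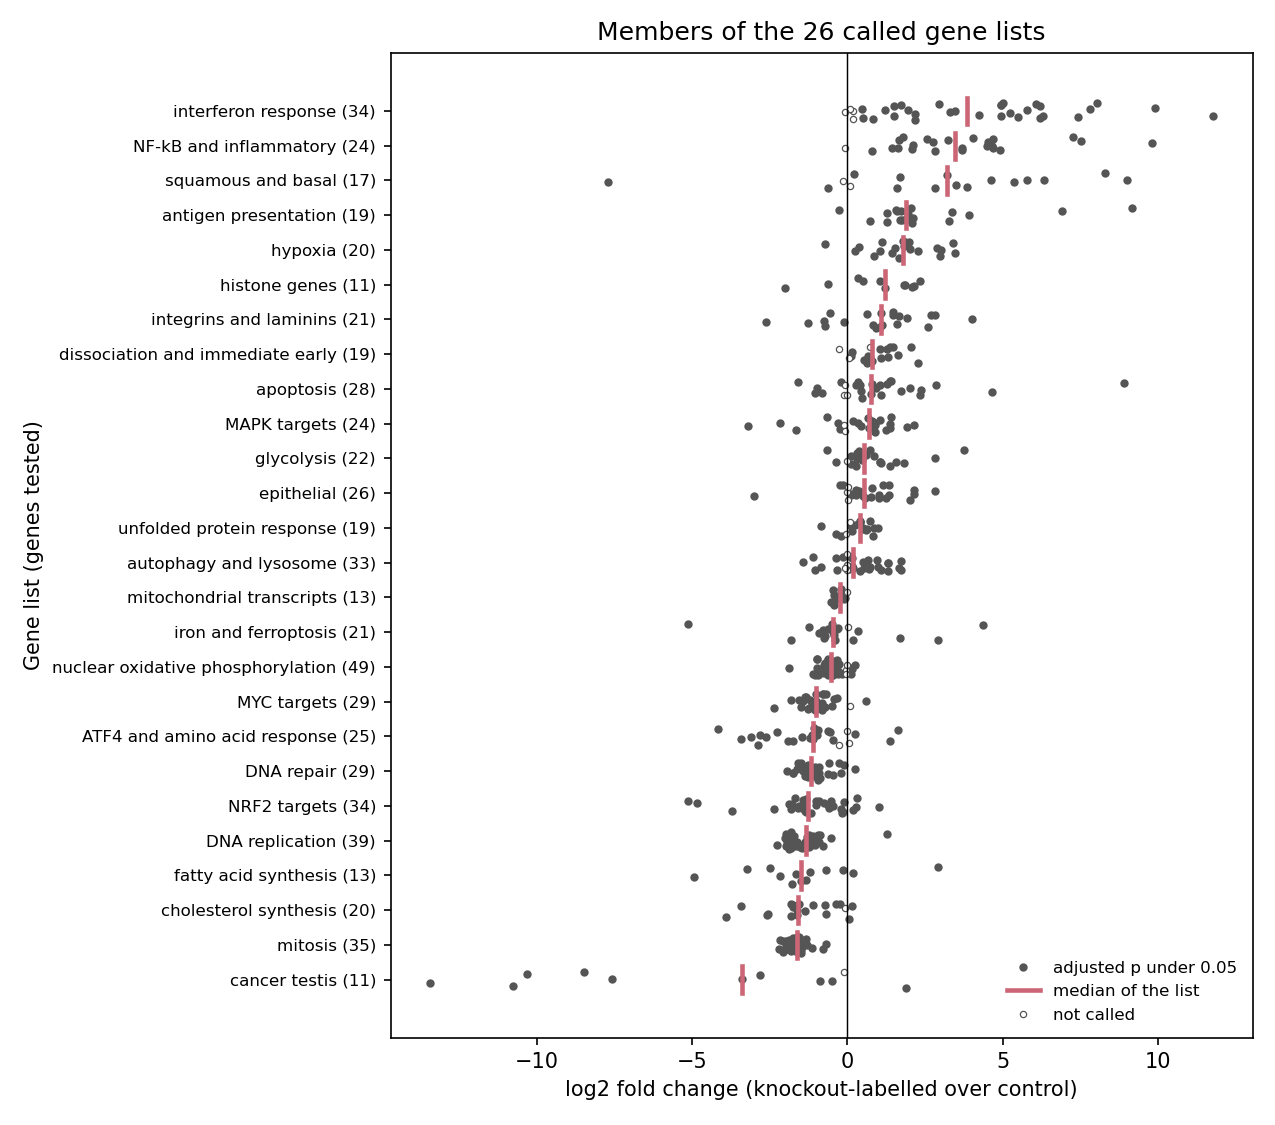
Log2 fold change (knockout-labelled over control) of each tested member of the 26 called gene lists, with 1 point per gene, filled where its adjusted p was under 0.05, and a bar at the list's median. List medians run from -3.38 for the cancer testis genes to 3.84 for the interferon response genes. Genes at 0 in a group are drawn at edgeR's fitted value, which is no bound.

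Stress and signalling lists were also called. Of 28 apoptosis genes, 20 rose and 5 fell, PMAIP1 by 2.86 and MCL1 by 1.28, with BAX falling by 0.97 (camera adjusted p = 0.003867, and 0.1211 with an estimated correlation). MCL1 is anti-apoptotic, while PMAIP1 and BAX promote apoptosis. Immediate early genes had 16 higher of 19, and 17 when adjusted over the list alone, with KLF4 rising by 2.28 and JUNB by 2.04 (camera adjusted p = 0.0001254, and 0.140 with an estimated correlation). Of 19 unfolded protein response genes, 14 rose and 3 fell, the chaperone gene HSPA5 by 0.83, with XBP1 falling by 0.85 (camera adjusted p = 0.01977, and 0.140 with an estimated correlation). Of 24 MAPK targets, 16 rose and 6 fell, DUSP6 by 2.14 and EPHA2 by 1.92, with ETV4 and ETV5 falling by 2.18 and 1.65 (camera adjusted p = 0.04206, and 0.1519 with an estimated correlation). Of 33 autophagy and lysosome genes, 22 rose and 7 fell, CTSD by 1.31 and PSAP by 1.30, with SQSTM1 falling by 1.42 (camera adjusted p = 0.03771, and 0.1694 with an estimated correlation). The MAPK call was lost without control replicate 1 or 3 or knockout replicate 2, at camera adjusted p of 0.0524 to 0.0555, and the autophagy call without control replicate 1, at 0.0582, and with scaling by library totals alone, at 0.0696.

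The other 19 tested lists were not called by camera. Among the chromatin lists, the CHD family had 4 higher and 2 lower of 9 (adjusted p = 0.6106), SWI/SNF subunits 7 higher and 13 lower of 23 (adjusted p = 0.1906), and Polycomb subunits 11 higher and 11 lower of 26 (adjusted p = 0.8514). The neighbours of CHD6 had 4 higher and 6 lower of 10 (adjusted p = 0.8514), and cytosolic ribosomal proteins 19 higher and 20 lower of 51 (adjusted p = 0.9385). Targets of p53 had 14 higher and 7 lower of 26 (adjusted p = 0.1858), and heat shock genes 3 higher and 10 lower of 15 (adjusted p = 0.09813). Mesenchymal genes had 15 higher and 7 lower of 24 (adjusted p = 0.1174), TGF-beta targets 9 and 5 of 15 (adjusted p = 0.1544), Notch targets 9 and 5 of 14 (adjusted p = 0.2084), YAP targets 12 and 8 of 21 (adjusted p = 0.2651) and Wnt targets 8 and 4 of 14 (adjusted p = 0.2852). Drug and steroid metabolism genes had 10 higher and 17 lower of 28 (adjusted p = 0.1222). Lung lineage genes had 7 higher and 6 lower of 15 (adjusted p = 0.8514), neuroendocrine genes 2 and 3 of 6 (adjusted p = 0.5729), gastrointestinal genes 6 and 2 of 10 (adjusted p = 0.2488) and endothelial markers 2 and 1 of 5 (adjusted p = 0.4999). The median and mean log2 fold change had opposite signs for the CHD6 neighbours (-0.10 and 0.09) and the lung lineage genes (0.31 and -0.003143). Fibroblast markers had 3 tested genes, of which DCN and LUM rose and COL1A1 fell by 1.32, and the markers of other cell lines had 4, of which SOX2 and CRABP2 fell, so neither list was tested as a group.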

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

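Scaling by library totals alone was chosen after the data were seen, and the other alternatives before. The count of changed genes was 10696 at an adjusted p under 0.01, and otherwise 10914 (filter of 1 CPM) to 11971 (no filter) against 11595. The 2-fold count ran from 3587 (filter of 1 CPM) to 4661 (no filter) against 4233, where the filter sets how many genes are tested. DESeq2 gave 11329 and 4169 and limma-voom 11646 and 4255. Leaving out 1 library at a time gave 11361 to 11404 changed genes, 4268 to 4331 at 2-fold, 23 to 26 lists and a CHD6 log2 fold change of 0.22 to 0.30. CHD6 stayed higher with an adjusted p under 0.05 in every fit in which it was recomputed. Of 26 lists called by camera, 8 were called with an estimated correlation (mitosis, DNA replication, NRF2 targets, cholesterol synthesis, hypoxia, interferon response, antigen presentation, NF-kB and inflammatory). A lost call does not by itself mean that a list's genes were more correlated than the preset 0.01. The estimate was below it for the squamous and basal (-0.00323), MAPK (0.00193) and epithelial (0.00986) lists, which lost their calls. Other lists that lost theirs had higher estimates, such as 0.371 for the mitochondrial transcripts. Fry, which does not compare lists with other genes, called 44 of 45. Among the lists it called, fry gave directions opposite to camera for the CHD6 neighbours (higher, adjusted p = 6.325e-05) and the lung lineage genes (lower, adjusted p = 1.875e-05), neither of which camera called. The cytosolic ribosomal proteins, called by neither test, also had opposite directions (fry adjusted p = 0.6696). Library totals alone gave 45.63% of calls higher against 50.13%, and a CHD6 log2 fold change of 0.19 against 0.27. The size of small fold changes thus depends on the scaling. Library totals alone also ended the calls of the autophagy (adjusted p = 0.0696) and iron lists (0.0553). Removal of each library's trend with GC content and length ended the same 2 calls (0.08145 and 0.07785) and no other list call, although, in a comparison chosen after the data were seen, their mean log2 fold changes relative to all genes were 0.1939 and -0.4166 before and 0.1975 and -0.4117 after. The replicate numbers did not pair the libraries, since the correlations of same-numbered libraries were 0.0331, -0.0374 and 0.0311, and not every library correlated best with its own number. With the replicate block, 11407 genes changed, 4205 of them at least 2-fold, and 26 lists were called, with no call changed among the lists and the named genes followed here. Of 1895 values of 146 named genes under the alternatives, 1888 kept their direction and their side of the threshold. Nearly all of these genes were picked by large changes or small p in the main fit of the same counts. The share kept was therefore bound to be high and does not speak for other genes. Depth limits what a count of 0 can show, where 3 counts over the knockout-labelled group are 0.0299 CPM. In the simulation 50% of 1.2-fold changes were missed. That share need not hold in the data, where 81.96% of genes changed against 50 simulated genes at each size.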

Other observations

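The groups of genes in the first 3 paragraphs, and the tests of mislabelling, of other cell types, of gene order and of loss along chromosome 2, were chosen after the values were seen, while the tests of depth, of GC content and length, and of other splits were chosen before, and the test of segment loss was chosen after the block was seen and before its own result. Of 17 complement and acute phase genes tested, out of 20 looked at, 14 rose, and CFB, of the alternative complement pathway, went from 2.61 ± 0.424 to 1879 ± 19.2 CPM, C3 from 115.5 ± 1.51 to 2528 ± 17.7 CPM and LCN2, an iron-siderophore binding protein, from 11.2 ± 0.813 to 606.5 ± 18.6 CPM. C5 and SERPINA3 fell, with log2 fold changes of -2.43 and -2.68, and ORM1 was not called. Of 16 S100 genes, 12 rose, 7 of them at least 2-fold, with S100A1 and S100A13 lower (log2 fold changes of -0.272 and -0.156) and 2 not called, and S100A9, the partner of S100A8, reached 11370 ± 76.4 CPM from 191 ± 1.11 CPM. Of 19 tested genes of the cornified envelope and skin proteases, 16 rose and 3 were not called. Among those that rose were PI3 from 1.42 ± 0.131 to 123 ± 3.85 CPM and CASP14 from 0.484 ± 0.170 to 72.9 ± 1.38 CPM. Of 9 tested guanylate-binding and APOL genes, 9 rose, APOL1 from 28.99 ± 2.21 to 2786 ± 23.6 CPM.

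Factors of interferon signalling did not all rise with the interferon-induced genes. Of 18 tested genes of interferons, sensors and signalling, out of 22 looked at, 11 rose, 3 fell and 4 were not called. Those that fell were MAVS, IRF3 and IFNLR1. IRF9 stood at 2.83 ± 1.40 CPM in the control libraries and 3.16 ± 0.551 CPM in the knockout-labelled libraries (edgeR adjusted p = 0.597). IRF1 rose from 16.3 ± 0.791 to 138 ± 4.19 CPM, and the RNA sensor genes RIGI and TLR3 had log2 fold changes of 4.22 and 5.19. IFNB1 had 0 counts in all 6 libraries, and IFNL1 reached 1.48 ± 0.216 CPM from 2 counts over the control group. DNMT1, the maintenance DNA methyltransferase gene, had a log2 fold change of -1.40. Of 7 tested DNA methylation genes, which include methyltransferases and genes of methyl removal, 5 were lower and 2 higher. The lower ones were DNMT1, DNMT3B and the removal genes TET1, TET3 and TDG. The methyltransferase gene DNMT3A rose by 0.67 and the removal gene TET2 by 0.40, so neither kind moved 1 way.

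BACH1, a repressor of HMOX1, rose from 28.3 ± 1.02 to 308 ± 3.03 CPM, beside the fall of HMOX1 from 397 to 11.3 CPM, and whether the 2 are linked was not tested. CDKN1A, the gene of the cell cycle inhibitor p21, rose 12.9-fold to 387 ± 3.93 CPM beside the fall of the mitosis genes. KEAP1 had 7 counts over the control group and 0 over the knockout-labelled group, while its neighbours PDE4A and ATG4D had 880 to 1828 and 474 to 758 counts per library. Whether KEAP1 is silent, deleted, edited or missed in counting was not tested. S1PR5, which lies between KEAP1 and ATG4D in GRCh38.p14, had 0 to 7 counts per library. CDKN2A, CDKN2B and MTAP had 0 counts in all 6 libraries.

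CHD6 RNA was higher, not lower, in the knockout-labelled libraries (log2 fold change 0.269). A single mislabelled library is argued against, since the lowest Spearman correlation within a group exceeded the highest between groups by 0.0397. An edited gene that still gives RNA and an exchange of the 2 groups' labels cannot be told apart by that value of 0.269, since neither group lost CHD6 RNA. Under exchanged labels the NRF2 targets would be higher, and the interferon genes lower, in the knockout. Reads by exon or a protein measurement, neither used here, would be needed.

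Inflammatory and squamous genes that rose from near 0 were part of 4233 changes of at least 2-fold. Unequal depth is argued against as the cause, since 98.3% of these calls were kept when every library was thinned to 28795584 counts. A trend with GC content and length is argued against as the whole cause. Its removal from each library kept 91.68% of the 4137 calls for genes with known GC content and length. Of 26 list calls, 24 were kept by the same removal. The calls of the autophagy and lysosome list (mean log2 fold change 0.3514, SE 0.1406 over genes, before and 0.2187, SE 0.1378, after, camera adjusted p = 0.08145) and of the iron and ferroptosis list (-0.2591, SE 0.3917, before and -0.3905, SE 0.3909, after, adjusted p = 0.07785) ended. In a comparison chosen after the values were seen, the mean of all genes moved from 0.1575 to 0.02116, and relative to it the autophagy list stood at 0.1939 before and 0.1975 after and the iron list at -0.4166 and -0.4117, so neither list lost its difference from all genes, and why the calls ended was not tested. Fibroblasts mixed into the cultures would bring collagen, yet COL1A2 and COL3A1 summed to 0.0786 CPM against 33.0 CPM of DCN, and COL1A1 fell from 35.1 to 14.01 CPM. Leukocytes would bring TYROBP and PTPRC, which summed to 0.159 CPM, and LCP1 and CORO1A fell. Yet ITGB2 rose from 10.7 ± 0.642 to 121 ± 5.47 CPM. Of the 9 tested leukocyte markers, 5 were higher, 4 of them at least 2-fold. Lower were 3, with 2 of them at least 2-fold, so the tested markers went both ways. A loss of CHD6 function, which the label names, remains open and was not tested. A difference between clones, passages, culture states or handling, editing steps included, on which the labels are silent, also remains open and untested.

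Neighbouring genes also moved together, most strongly on chromosome 2. The 8601 tested genes with a GRCh38.p14 position on chromosomes 1 to 22 or X and an average log2 CPM above 4 were put in order. In 204 blocks of 40 such genes, the block from ACTR3 to HNMT had a median log2 fold change of -0.86, with 92.5% of its genes lower, and chance order is argued against by a permutation p of 0.001, the smallest that 1000 random orders can give. GC content and length are argued against, since the median was -0.999 after their removal. A loss of copies along the whole chromosome is also argued against, since only 3 of its 14 blocks had medians below -0.3 before that removal. After it more blocks did, such as FAM110C to SDC1 at -0.4408 and PUM2 to SLC4A1AP at -0.4146, which weakens this argument. Others did not, such as PMS1 to NDUFS1 at -0.05559 and PEX13 to PAIP2B at -0.1099. Loss of a chromosome segment in the knockout-labelled cells stays open. The 20 tested genes inside the segment that were too low to help pick the block had a median log2 fold change of 0.06692 against 0.178 for 5020 equally low genes elsewhere (a difference of -0.1111, 95% bootstrap interval -1.694 to 0.6988, one-sided permutation p = 0.3437), which is too wide to decide. A shared regulation of the block was not tested. In all, 7 blocks lay beyond the limit of random orders, 4 lower and 3 higher.

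With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 11595 changed genes and 4233 at 2-fold, where the highest of the other splits gave 0 and 0, and 1 of 10 splits gave as many in each case. Every other split puts libraries of both groups on each side, so the large group difference adds to the spread within sides. Few or no gene calls would then be made whatever the cause of that difference, so these 0 counts do not show what chance gives. For gene lists the real split gave 26 and the highest other split 21, and 1 of 10 gave as many. The sides of the other splits hold unequal numbers of each group, so part of the group difference stays between them. Their list calls are therefore no measure of chance either.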
